A study of Mus musculus with 13 samples.

How the data were processed

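RNA was measured by sequencing in 13 samples of primary mouse astrocyte cultures, 4 given vehicle and 3 each given SB431542, HLM006474 or an inhibitor of RUNX1 and CBFB (the RUNX1 inhibitor) for 24 h. Per the labels, the cells came from retinas and optic nerves of wild-type C57BL/6 pups, were grown in medium with serum, and total RNA was taken up into Illumina libraries by an outside company. Per the submitters' processing notes, the tools were CASAVA 1.8, STAR 2.7 and DESeq2 1.30.1, and the genome build was GRCm38. Library strandedness, the read counter and its gene annotation are not given in the sources used here.

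The files used are 3 tables of the authors' own comparisons, each of 1 compound against vehicle. The authors' deposited tables give for each gene a mean normalised count, which is a signal level averaged over libraries, per the file headers. They also give a log2 fold change with its standard error, on the log2 scale, per the file headers. A Wald score, deposited by the authors, is the fold change divided by that error. The p-value and the adjusted p-value are also the authors' own, per the file headers. The mean count of a gene is identical in all 3 tables, so the fold changes come from 1 fit that includes all groups. Every gene in the authors' deposited tables has an adjusted p under 0.05 and a fold change of at least about 1.5, so the tables hold part of the genes tested. Values per sample were not analysed here. The depth of each library is therefore unknown, no replicate value or SD is given, and precision is stated by the authors' standard errors. Whether samples of a group came from separate animals or separate platings is not stated in the labels, so p-values measure the spread between these samples, which may be technical.

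The tests fixed before the data were examined foresaw either counts or tables of fold changes, and the form for tables of fold changes was used. Genes were counted by direction at the authors' adjusted p, with no new test per gene. A set of 21 gene lists and 9 marker lists was fixed before the data were examined. The direction of a list was tested with the 2-sided Fisher's exact test, which sets listed members, higher or lower, against the other genes of the same table. It was run for lists with at least 3 members in a table, 35 tests in all, with Benjamini-Hochberg adjustment. Because this test compares directions among called genes only, it has less power for a falling list in a table where most genes are lower. The number of list members that would pass when adjusted over the list alone was not computed, because the p-values of members outside the tables were not analysed here.

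The ratio of p to adjusted p gives the rank of a gene and the number of genes tested. The smallest number that makes most of the checked ranks whole within 0.02 was 15169 genes for SB431542, 13561 for the RUNX1 inhibitor and 15169 for HLM006474. It made 82.2%, 83.9% and 79.6% of those ranks whole in that order, and no other number save its multiples made more than 16.1% whole. Genes called tested here are those that entered the adjustment of p. The smallest mean count was 21.6 in the RUNX1 inhibitor table, against 5.12 for SB431542 and 5.09 for HLM006474. Genes with low counts may therefore have been left out of the adjustment for the RUNX1 inhibitor. With the number tested, a 1-sided exact hypergeometric test of how many list members are in a table was added after the data were seen, over 90 combinations of list and compound. It takes every list member as tested, which raises the expected number and is cautious on that point. Both list tests treat genes as independent. List members that move together can make the p-values of both tests too small.

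A difference between 2 compounds was tested for genes in both tables with a 2-sided z test on the difference of the log2 fold changes. Its standard error is the root of the summed squares, which leaves out the shared vehicle libraries and is too large where the groups vary alike. Benjamini-Hochberg adjustment was made within each pair. For genes in only 1 of 2 tables, a bound was added after the data were seen. A gene outside a table was taken to lie under that table's fold limit or under its p limit. Its standard error was taken from the other comparison. Genes with a mean count under the smallest in that table were left out, since a low count may also explain their absence. The standard errors of genes in both tables had a median ratio of 1.00, with 5th and 95th percentiles of 0.955 and 1.06. A gene passes only if its change exceeds that limit by more than the error of the difference. Overlap of tables was set beside the number expected for independent lists and beside 1000 simulated draws of unchanged groups that share the vehicle libraries. The fold limit was not applied in those draws, which raises their overlap. All their genes were unchanged, however, so their overlap was on average below the number expected for independent lists. The simulated numbers are therefore no upper limit of chance overlap between the real tables. A split of the vehicle libraries needs values per sample, and part of any excess may come from the shared controls.

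The procedures were tested on 10 simulated pairs of tables, the largest with 15143 genes. The number of genes tested was recovered exactly in all 10, and the number past adjusted p fell short by at most 2. Of simulated genes with equal effects in both tables, 0.056% were called different. Of genes changed 4-fold in one table and 2-fold in the other, 82.9% were called. The bound called 74.9% of listed genes with a 4-fold change in 1 table only, but 11.1% of those with a 2-fold change. Among random lists of listed genes, 4.33% passed an unadjusted p of 0.05 in the direction test. Such lists hold no genes chosen to move together, so this rate does not cover lists of co-regulated genes.

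Named genes followed a rule fixed before the data were examined, and gene models with provisional names were left out. Per compound it takes the 5 largest rises and falls among genes at or above the table's median mean count, and the 5 lowest adjusted p in each direction. It adds up to 4 members of each list with the largest changes, all members of the inhibitors' target families, genes moving one way in all 3 tables, and the largest differences between compounds. Of 1592 symbols, 1577 matched 1 gene of GENCODE release M21 on GRCm38, the same build, and positions come from that annotation. Alternatives that need no counts were run: an adjusted p under 0.01, a fold limit of 1.5 or 2, a limit at the lower quartile of mean count, lists without shared members, and a difference test with the vehicle covariance taken out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.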

Results

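Gene expression was measured in cultured mouse astrocytes, the star-shaped glia of the nervous system, grown from neonatal retinas and optic nerves. There were 4 vehicle samples and 3 samples for each of 3 small-molecule inhibitors, all after 24 h. SB431542 blocks the kinase of the type I receptors for TGF-beta and activin. Another compound, called the RUNX1 inhibitor in the text, is an inhibitor of the RUNX1 transcription factor and its partner CBFB. Whether its effects came through these proteins was not tested. HLM006474 is an inhibitor of E2F transcription factors, which drive genes of DNA replication. The comparisons ask which genes each inhibitor changed against vehicle, and how the inhibitors differed. Fold changes are on the log2 scale and are given as value ± standard error, both from the authors' deposited tables. The depth of the libraries is unknown from these tables, and doses are not stated in the labels. Transcripts of microglia and macrophages were also present, with mean counts of 24249 for Lyz2 and 7075 for C1qa. The astrocyte identity genes Fabp7 and Kcnj10 had mean counts of 18965 and 23892.5. The cell type in which a gene changed cannot be told from these values.

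SB431542 lowered TGF-beta response genes and extracellular matrix genes. Pmepa1, a TGF-beta-induced membrane protein that restrains SMAD signalling, stood at -3.43 ± 0.11 in the authors' deposited table. Mrc1, the macrophage mannose receptor, rose by 2.64 ± 0.11, and Slc40a1, the iron exporter ferroportin, by 2.90 ± 0.15, in the authors' deposited table. The microglial surface protein Tmem119 had the largest fall among genes above the median count, -4.00 ± 0.11 in the authors' deposited table.

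In all, 748 genes were listed for SB431542, 347 higher and 401 lower, of 15169 tested. Of the 30 TGF-beta response genes 11 were listed, all lower, where 1.48 were expected. They included the matrix protein gene Tgfbi at -1.94 ± 0.076 and Lrrc15 at -2.32 ± 0.31 in the authors' deposited table. That direction differed from the other listed genes (Fisher's exact test, adjusted p = 0.00827). Of the 46 extracellular matrix genes 22 were listed, all lower, where 2.27 were expected (Fisher's exact test of direction, adjusted p = 1.52e-05). The collagen cross-linking enzymes Lox and Loxl1 stood at -1.78 ± 0.063 and -1.29 ± 0.063 in the authors' deposited table. Plod2, a lysyl hydroxylase of collagen, and Col1a1, a chain of type I collagen, stood at -1.09 ± 0.051 and -1.08 ± 0.054 in the authors' deposited table. The receptor gene Tgfbr1 itself, one of the inhibitor's targets, stood at -1.01 ± 0.071 in the authors' deposited table. Among other target families Runx3 stood at -0.72 ± 0.26 and Runx2 at -0.66 ± 0.19 in the authors' deposited table. The lowest adjusted p values for falling genes also included the matricellular gene Ccn5 at -1.10 ± 0.033, the prion protein gene Prnp at -1.01 ± 0.034 and the integrin gene Itgb5 at -0.84 ± 0.029, in the authors' deposited table. The basement membrane collagen gene Col7a1 stood at -2.52 ± 0.32 and the junction gene F11r at -2.22 ± 0.17 in the authors' deposited table. The 3 listed contractile genes were lower, with Actg2 at -0.71 ± 0.19, Acta2 at -0.64 ± 0.078 and Tagln at -0.63 ± 0.074 in the authors' deposited table, and this list did not pass the direction test (Fisher's exact test, adjusted p = 0.466).

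On the rising side 7 of 25 interferon response genes were listed, all higher, where 1.23 were expected (Fisher's exact test, adjusted p = 0.0224). Among them were the antiviral genes Rsad2 at 1.20 ± 0.25 and Mx1 at 2.37 ± 0.92, and Psmb9, an immunoproteasome subunit, at 0.91 ± 0.16, in the authors' deposited table. Mx1 rests on few reads. The interferon result ended when genes in several lists were left out (adjusted p = 0.0613, Fisher's exact test). Of 26 NF-kB and inflammatory mediators 5 were listed, all higher, and the direction test did not pass (Fisher's exact test, adjusted p = 0.0673). Their number exceeded the 1.28 expected (exact hypergeometric test, adjusted p = 0.0383). The chemokines Ccl7 and Ccl2 stood at 3.27 ± 0.47 and 2.28 ± 0.22, and the cytokine gene Tnf at 1.20 ± 0.29, in the authors' deposited table. Other large rises were the chemokines Ccl9 at 2.62 ± 0.20 and Ccl6 at 2.48 ± 0.17, with Wfdc17 at 2.35 ± 0.19, in the authors' deposited table. The lowest adjusted p values for rising genes included Lilr4b at 1.97 ± 0.10, properdin (Cfp) at 1.95 ± 0.10 and the metalloprotease gene Adam8 at 1.39 ± 0.066, in the authors' deposited table. Beside these genes, 5 of 14 microglia and macrophage markers were listed, where 0.69 were expected (exact hypergeometric test, adjusted p = 0.00298), 3 lower and 2 higher. The fractalkine receptor gene Cx3cr1 stood at -2.21 ± 0.081, P2ry12 at -1.19 ± 0.17 and the complement gene C1qa at -0.66 ± 0.052 in the authors' deposited table. Lysosomal Cd68 was higher, 0.72 ± 0.075 in the authors' deposited table. Of 33 integrated stress and unfolded protein response genes 5 were higher and 1 lower (Fisher's exact test, adjusted p = 0.273). Their number exceeded the 1.63 expected (exact hypergeometric test, adjusted p = 0.0280), and the regulator Atf3 stood at 1.02 ± 0.091 in the authors' deposited table. No member of the E2F and mitosis lists was in the SB431542 table, whose limits exclude smaller changes.

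**Figure D1:**
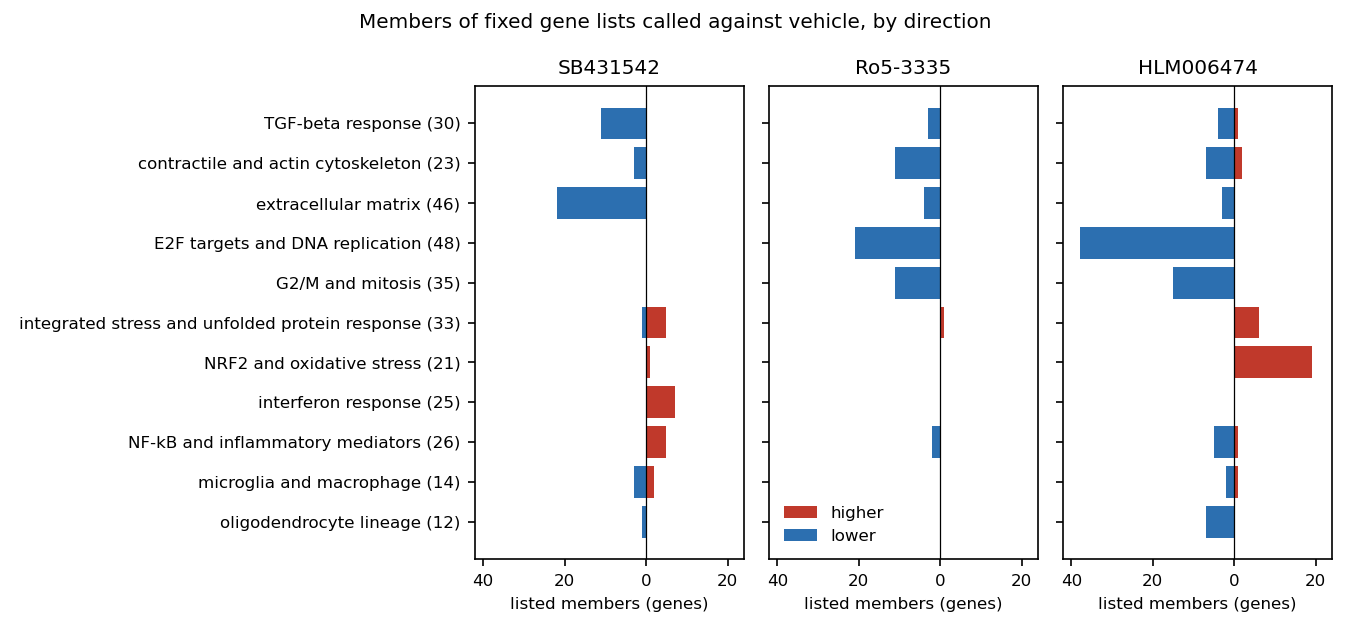
Number of members of fixed gene lists in each compound's table, with higher genes to the right of 0 and lower genes to the left. Numbers after list names are list sizes, and lists with at least 5 members in any 1 table are drawn. HLM006474 has 38 lower genes in the E2F list and 19 higher genes in the NRF2 list, and SB431542 has 22 lower matrix genes.

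The RUNX1 inhibitor lowered 11 of 23 contractile genes and 21 of 48 E2F target and DNA replication genes. Smooth muscle actin, Acta2, stood at -1.19 ± 0.078 and the actin-binding gene Tagln at -1.13 ± 0.075 in the authors' deposited table. The replication enzyme genes Tk1 and Rrm2 stood at -0.97 ± 0.11 and -0.95 ± 0.077 in the authors' deposited table. The largest rise among genes above the median count was Alpl, tissue-nonspecific alkaline phosphatase, at 2.78 ± 0.40 in the authors' deposited table. Its error was large for a mean count of 1139, beside 0.082 for Tpm2 at a mean count of 1410. Whether all samples shared the rise of Alpl is unknown, because values per sample were not analysed here.

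There were 397 genes listed for the RUNX1 inhibitor, 82 higher and 315 lower, of 13561 tested. Of the 23 contractile and actin genes 11 were listed, all lower, where 0.673 were expected. Myosin light chain Myl9 stood at -1.03 ± 0.072, tropomyosins Tpm2 and Tpm4 at -1.12 ± 0.082 and -0.62 ± 0.035, and calponin Cnn2 at -0.79 ± 0.045, in the authors' deposited table. Enteric actin Actg2 stood at -1.37 ± 0.20 in the authors' deposited table. In a table where 79.3% of genes were lower, this direction did not differ from the rest (Fisher's exact test, adjusted p = 0.304), while the number listed exceeded expectation (exact hypergeometric test, adjusted p = 2.09e-10). Of the 48 E2F target and replication genes 21 were listed, all lower, where 1.41 were expected. Their direction test gave an adjusted p of 0.0473 by Fisher's exact test, and their number an adjusted p of 1.20e-18 by the exact hypergeometric test. The direction call ended with an adjusted p under 0.01 per gene, with the mean count limit and without genes in several lists (adjusted p = 0.0953, 0.0579 and 0.0611, Fisher's exact test). Uhrf1, which recruits the maintenance DNA methyltransferase, stood at -0.87 ± 0.080 in the authors' deposited table. E2f8 was the 1 listed member of the inhibitors' target families, at -0.89 ± 0.13 in the authors' deposited table, and neither Runx1 nor Cbfb was in this table. Of 35 mitosis genes 11 were listed, all lower, where 1.02 were expected (direction by Fisher's exact test, adjusted p = 0.304). Cyclin A2 (Ccna2) stood at -0.73 ± 0.056 and the mitotic kinase gene Plk1 at -0.77 ± 0.12 in the authors' deposited table. The 4 listed matrix genes were lower, among them Tnc, tenascin C, at -0.79 ± 0.065 in the authors' deposited table. The 3 listed TGF-beta response genes were lower, with Lrrc15 at -0.96 ± 0.27 and Ltbp2 at -0.85 ± 0.079 in the authors' deposited table. Neither list passed the direction test, at adjusted p = 0.787 and 1 by Fisher's exact test.

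Among other large falls were the calcium-handling genes Casq1 and Jph2 at -1.25 ± 0.14 and -1.22 ± 0.16 in the authors' deposited table. Adamts14, a procollagen protease gene, stood at -1.16 ± 0.16 in the authors' deposited table. Rising genes included the immediate early transcription factor genes Fosb at 2.19 ± 0.27, Nr4a1 at 1.20 ± 0.20 and Egr2 at 1.10 ± 0.19, in the authors' deposited table. Arrdc3, an arrestin-domain gene, rose by 1.33 ± 0.081 in the authors' deposited table. Polr2a, the largest subunit of RNA polymerase II, and Sat1, an enzyme of polyamine breakdown, stood at 0.60 ± 0.049 and 0.60 ± 0.055 in the authors' deposited table.

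HLM006474 lowered most of the E2F target and replication genes and raised nearly all of the oxidative stress genes on the NRF2 list. Cdc6, a replication licensing factor, stood at -1.49 ± 0.13 and thymidine kinase Tk1 at -1.34 ± 0.12 in the authors' deposited table. Hmox1, the heme-degrading enzyme heme oxygenase 1, rose by 2.77 ± 0.15 and sulfiredoxin Srxn1 by 2.12 ± 0.10 in the authors' deposited table. Of 12 oligodendrocyte lineage markers 7 were lower, with Mbp, myelin basic protein, at -1.20 ± 0.35 in the authors' deposited table.

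The HLM006474 table lists 856 genes, 216 higher and 640 lower, of 15169 tested. Of the 48 E2F target and replication genes 38 were listed, all lower, where 2.71 were expected (Fisher's exact test of direction, adjusted p = 0.000277). The helicase subunit Mcm2 stood at -1.05 ± 0.065 and Uhrf1 at -1.24 ± 0.081 in the authors' deposited table. In the inhibitors' target families E2f2 was lower, E2f8 stood at -1.23 ± 0.13, Runx3 at -0.98 ± 0.27 and E2f7 at -0.75 ± 0.24 in the authors' deposited table. Of 35 mitosis genes 15 were lower and none higher, where 1.98 were expected, and the direction test did not pass (Fisher's exact test, adjusted p = 0.0573). The proliferation marker Mki67 stood at -1.11 ± 0.092 and Ccna2 at -0.85 ± 0.056 in the authors' deposited table.

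On the NRF2 list 19 of 21 genes were listed, all higher, where 1.19 were expected (Fisher's exact test of direction, adjusted p = 8.22e-11). The quinone reductase gene Nqo1 stood at 1.99 ± 0.13 and the cystine transporter gene Slc7a11 at 1.48 ± 0.23 in the authors' deposited table. Gclc, which makes the first step of glutathione synthesis, and thioredoxin reductase Txnrd1 rose by 0.92 ± 0.049 and 1.03 ± 0.057 in the authors' deposited table. Of 33 integrated stress and unfolded protein response genes 6 were listed, all higher (Fisher's exact test, adjusted p = 0.00214). Their number exceeded the 1.86 expected (exact hypergeometric test, adjusted p = 0.0427). They were Ddit4, Atf5, Ddit3, Slc7a11, which is also on the NRF2 list, Trib3 at 1.15 ± 0.29 and Atf3 at 1.03 ± 0.091 in the authors' deposited table. The chaperone genes Hspa5 and Hsp90b1 of this list were not in the table, so an unfolded protein response was not shown. Of 10 aryl hydrocarbon receptor targets 4 were higher (Fisher's exact test, adjusted p = 0.0224), with Cyp1b1 at 0.61 ± 0.034 in the authors' deposited table. Nqo1 belongs to this list and to the NRF2 list. The aryl hydrocarbon call ended under 3 alternatives (adjusted p = 0.0532, 0.0566 and 0.0594, Fisher's exact test). Of 22 p53 targets 3 were higher (Fisher's exact test, adjusted p = 0.0573), among them Mdm2 at 0.65 ± 0.073 and Gdf15 at 1.26 ± 0.21 in the authors' deposited table. Among other rising genes were Lipa, lysosomal acid lipase, at 0.91 ± 0.044 and Slc40a1 at 2.02 ± 0.15 in the authors' deposited table. Fosb had the largest rise among genes above the median count, 3.22 ± 0.26 in the authors' deposited table.

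Of 23 contractile genes 7 were lower and 2 higher, with Actg2 at -1.88 ± 0.20 and Acta2 at -1.09 ± 0.078 in the authors' deposited table (Fisher's exact test, adjusted p = 1). Des and Ankrd1 were the higher ones, at 2.19 ± 0.74 and 2.46 ± 0.92 in the authors' deposited table. Of 26 inflammatory mediators 5 were lower and 1 higher, with Ccl2 at -1.06 ± 0.24 and Ptgs2 at 0.79 ± 0.17 in the authors' deposited table (Fisher's exact test, adjusted p = 1). The number of mediators listed exceeded the 1.47 expected (exact hypergeometric test, adjusted p = 0.0177). Of 12 oligodendrocyte lineage markers 7 were lower and none higher, where 0.677 were expected. Their direction did not differ from other listed genes (Fisher's exact test, adjusted p = 0.415), but their number exceeded expectation (exact hypergeometric test, adjusted p = 1.10e-05). Sox10, the lineage transcription factor, stood at -1.10 ± 0.18 and Mobp at -1.80 ± 0.53 in the authors' deposited table. Microglial Tmem119 stood at -1.08 ± 0.070, Aif1 at -0.89 ± 0.15 and Lyz2 at 1.08 ± 0.18 in the authors' deposited table. Other large falls were the neurotrophic factor gene Ndnf at -1.73 ± 0.29, the cell cycle inhibitor gene Cdkn1c at -1.38 ± 0.23 and Psd4 at -1.38 ± 0.19, in the authors' deposited table.

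**Figure D2:**
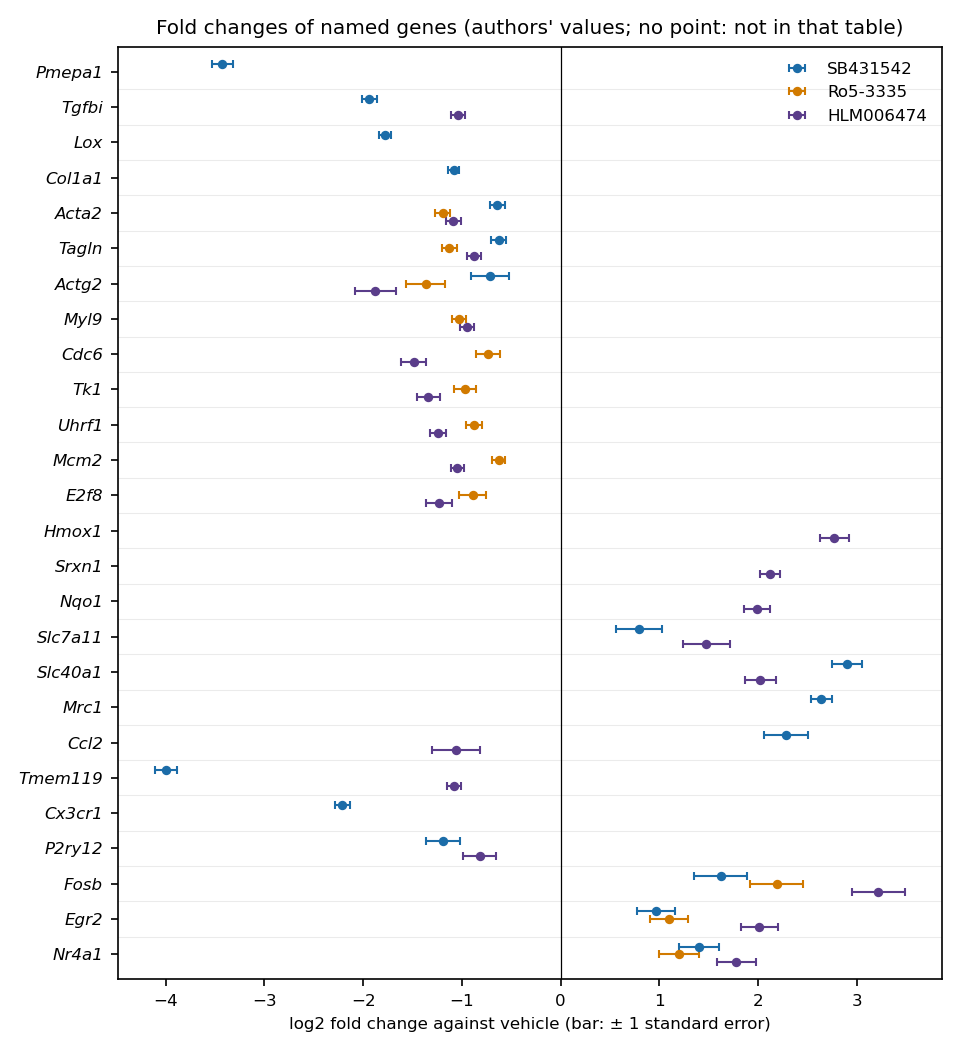
Log2 fold change against vehicle of named genes under SB431542 (blue), the RUNX1 inhibitor (orange) and HLM006474 (purple), points with bars of 1 standard error, from the authors' deposited tables. A missing point means that the gene is outside that table's limits. Pmepa1 stands at -3.43 under SB431542 and Hmox1 at 2.77 under HLM006474, with no point for the other compounds.

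Of 30 astrocyte identity genes SB431542 listed Thbs2 and Kcnj10, a potassium channel gene, at -0.78 ± 0.058 and -0.77 ± 0.037 in the authors' deposited table. The RUNX1 inhibitor listed Fabp7, a fatty acid binding protein gene, at -0.67 ± 0.055 in the authors' deposited table. HLM006474 listed Thbs2, Fabp7 and Slc6a11, all lower, with Fabp7 at -0.64 ± 0.055 in the authors' deposited table. On the reactive astrocyte lists, SB431542 lowered Timp1, Hspb1 and Fbln5, at -0.98 ± 0.10, -1.08 ± 0.13 and -0.93 ± 0.067 in the authors' deposited table. It raised Cxcl10, Gbp2 and Cd14, at 0.80 ± 0.20, 0.65 ± 0.081 and 0.99 ± 0.099 in the authors' deposited table. Also on those lists, HLM006474 lowered Steap4 and Tgm1 and raised Clcf1 and Ptgs2, and the RUNX1 inhibitor lowered Hspb1 and Tgm1. The activin subunit gene Inhba was lower under all 3 compounds, at -1.12 ± 0.26, -0.94 ± 0.26 and -0.99 ± 0.26 in the authors' deposited tables. Gdf6 and Pdgfb, also on the growth factor list, were lower under HLM006474. Among BMP genes Bmp2 was higher under SB431542, at 1.65 ± 0.28, and Msx2 under HLM006474, at 0.65 ± 0.17, in the authors' deposited tables. Cholesterol synthesis genes Fdps, Lss and Nsdhl were lower under HLM006474, with Fdps at -0.79 ± 0.065 in the authors' deposited table (Fisher's exact test, adjusted p = 0.787). On the hypoxia and glycolysis list 3 genes were higher and 1 lower under HLM006474, with the glucose transporter gene Slc2a1 at 0.75 ± 0.065 in the authors' deposited table (Fisher's exact test, adjusted p = 0.151). Of p53 targets, Gdf15 was higher under SB431542 and Gadd45a under the RUNX1 inhibitor. Trib3 was the 1 listed stress response gene under the RUNX1 inhibitor, and Tnfaip3 and Il33, both lower, its listed inflammatory mediators. Under HLM006474, 3 matrix genes were lower, and of the TGF-beta response genes 4 were lower and Klf10 higher. On the aryl hydrocarbon list SB431542 lowered Cyp1b1 and raised Ahrr. Of heat shock genes, Hspb1 was listed under SB431542 and the RUNX1 inhibitor, where it stood at -0.98 ± 0.13 in the authors' deposited table.

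Markers of other cell types were also in the tables. Several of them are also on lists given above, so their changes are not separate results. Fibroblast markers Col1a1 and Col1a2 were lower under SB431542, and Pdgfra under HLM006474 at -0.84 ± 0.14, in the authors' deposited tables. Col1a1 and Col1a2 are also on the extracellular matrix list, and Pdgfra on the oligodendrocyte lineage list. Endothelial Flt1 was lower under SB431542 and the RUNX1 inhibitor, at -1.17 ± 0.41 and -1.12 ± 0.41 in the authors' deposited tables. Of 8 pericyte and smooth muscle markers 3 were listed under SB431542 and 3 under HLM006474, more than expected (exact hypergeometric test, adjusted p = 0.0294 and 0.0383). Cspg4 was lower under both, at -1.04 ± 0.14 and -1.01 ± 0.14 in the authors' deposited tables. Under SB431542 Notch3 was lower, at -0.63 ± 0.070, and Anpep higher, at 2.04 ± 0.55, and under HLM006474 Myh11 and Rgs5 were lower, at -1.37 ± 0.54 and -0.60 ± 0.21, in the authors' deposited tables. Cspg4 is also on the oligodendrocyte lineage list, and Myh11 on the contractile list. The Müller glia gene Crym was lower under the RUNX1 inhibitor and HLM006474, at -0.75 ± 0.13 and -1.35 ± 0.13 in the authors' deposited tables. Neuronal genes were Nefl, higher under SB431542, Tubb3, lower under the RUNX1 inhibitor, and Syt1, lower under HLM006474. Of 6 Schwann cell markers 3 were listed under HLM006474, Egr2, Prx and Sox10, more than expected (exact hypergeometric test, adjusted p = 0.0189). These 3 did not move one way, and Sox10, which was lower, is also on the oligodendrocyte lineage list. On the Schwann cell list Egr2 was higher under all 3 compounds, and Prx was lower under the RUNX1 inhibitor and HLM006474. No pigment epithelium or melanocyte marker was in any table.

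The RUNX1 inhibitor and HLM006474 moved many of the same genes the same way, and SB431542 differed from HLM006474 in Ccl2 and Tnf, which moved in opposite directions. The RUNX1 inhibitor and HLM006474 shared 211 genes, of which 32 were higher under both, 176 lower under both and 3 opposite. Independent lists would share 25.1 genes, and simulated unchanged groups with the same vehicle libraries shared 11.4 on average and 23 at most. HLM006474 and SB431542 shared 161 genes, 48 higher under both, 93 lower under both and 20 opposite. Independent lists would share 42.2, and simulated ones at most 22. The RUNX1 inhibitor and SB431542 shared 93, of which 24 were higher under both, 65 lower under both and 4 opposite, against 21.9 expected and at most 20 simulated. The same-direction shares were 98.6%, 87.6% and 95.7% in that order, against 99.97%, 99.99% and 99.98% among simulated unchanged groups. Unchanged genes pass for both compounds mainly through the shared vehicle samples, so their directions agree almost by design. The share agreeing in direction therefore cannot separate a shared response from shared vehicle samples. Part of each excess of shared genes may come from the shared vehicle samples. The simulated groups held unchanged genes only, so their numbers are no upper limit of chance overlap between the real tables.

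The size of the response differed for 20 of the 211 genes shared by HLM006474 and the RUNX1 inhibitor, 53 of the 161 shared by HLM006474 and SB431542, and 16 of the 93 shared by the RUNX1 inhibitor and SB431542, at an adjusted p under 0.05. With the vehicle covariance taken out the first count was 34, and at an adjusted p under 0.01 it was 7. Of the 21 E2F list genes in both the HLM006474 and the RUNX1 inhibitor tables, 19 were lower under HLM006474 than under the RUNX1 inhibitor and 2 higher. The median difference over all 21 was -0.35, and 6 differed (Uhrf1, Mcm2, Mcm5, Cdc6, Chaf1b and Mcm3). Ccl2 fell under HLM006474 and rose under SB431542, and the difference was -3.34 ± 0.33 (adjusted p = 4.85e-23, from the standard errors of the fitted model). Tmem119 was lower under both and 2.92 ± 0.13 log2 units further down under SB431542 (adjusted p = 2.30e-110).

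Genes in 1 table only were compared through the other table's limits. Of the NRF2 genes listed for HLM006474, 8 of 19 exceeded what the limits of the RUNX1 inhibitor table allow, and 8 of the 18 outside the SB431542 table exceeded what its limits allow. Of the SB431542 matrix genes, 15 of 20 exceeded the limits for the RUNX1 inhibitor and 14 of 20 those for HLM006474. Of the TGF-beta response genes, 6 of 9 and 5 of 8 did. For the E2F list, 13 of the 38 genes listed for HLM006474 differed from SB431542. None of the 21 listed for the RUNX1 inhibitor did, so a difference between the RUNX1 inhibitor and SB431542 was not shown for these genes.

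In all 3 tables stood 57 genes, 17 higher under every compound, 38 lower under every compound and 2 mixed. Independent lists would give 1.38, and simulated unchanged groups gave at most 7. Those groups held unchanged genes only, so their number is no upper limit of chance overlap. Of the 57, the higher genes with the largest changes were Fosb, Nr4a1, Egr2, Egr3 and Trib3. Egr3 stood at 1.27 ± 0.17, 0.86 ± 0.18 and 1.68 ± 0.17 under SB431542, the RUNX1 inhibitor and HLM006474 in the authors' deposited tables. The lower ones were Pakap, Ch25h, Stra6, Lrrc15 and Ptprb. Ch25h, cholesterol 25-hydroxylase, stood at -1.30 ± 0.20, -1.21 ± 0.20 and -1.84 ± 0.21 in the authors' deposited tables. Stra6, the retinol uptake receptor, stood at -2.20 ± 0.23, -0.90 ± 0.22 and -1.23 ± 0.22 in the authors' deposited tables.

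**Figure D3:**
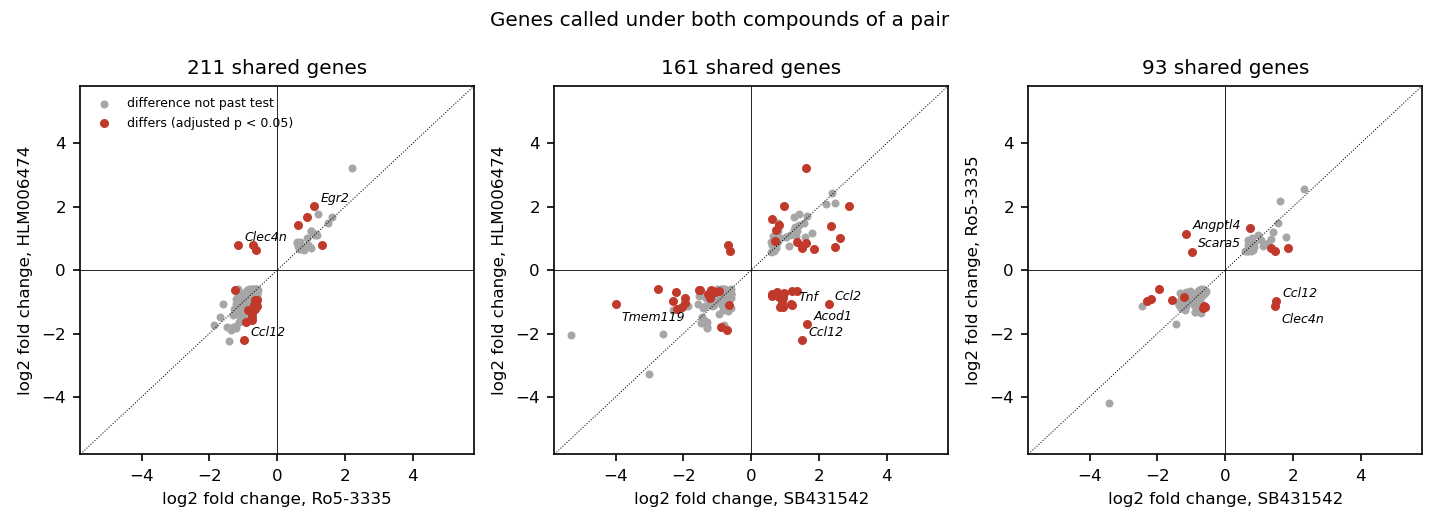
Log2 fold changes of genes in both tables of a pair, 211, 161 and 93 genes, with 1 compound on each axis and the dotted line marking equal change. Red points differ between the compounds at an adjusted p under 0.05. Ccl2, Tnf, Acod1 and Ccl12 lie on opposite sides of 0 under HLM006474 and SB431542.

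On GRCm38 the genes with leading values lie at these places, each a protein-coding gene given by its whole span in the GENCODE annotation. Pmepa1 lies on chromosome 2, 173224458 to 173276533 and Tmem119 on chromosome 5, 113793729 to 113800516. Acta2 lies on chromosome 19, 34241090 to 34255590 and Alpl on chromosome 4, 137741733 to 137796384. Cdc6 lies on chromosome 11, 98907801 to 98923940, Tk1 on chromosome 11, 117815526 to 117826092, Hmox1 on chromosome 8, 75093621 to 75100589 and Srxn1 on chromosome 2, 152105516 to 152111376.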

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

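The differences between compounds were planned before the data were examined, and the tests of explanations were chosen after the results were seen. In each case below the fold changes under 2 compounds differed by the z test of the difference. Between HLM006474 and the RUNX1 inhibitor the difference, first minus second, was 1.94 ± 0.42 for the lectin gene Clec4n, 1.51 ± 0.33 for Eef1a2 and 1.26 ± 0.33 for Ptgfr, each higher under the first and lower under the second. It was -1.24 ± 0.40 for the chemokine gene Ccl12 and 0.92 ± 0.27 for Egr2. Between HLM006474 and SB431542 it was -3.71 ± 0.38 for Ccl12, -3.36 ± 0.79 for Acod1, -3.34 ± 0.33 for Ccl2 and -2.30 ± 0.46 for Tnf, all lower under HLM006474 and higher under SB431542. For Tmem119 it was 2.92 ± 0.13. Between the RUNX1 inhibitor and SB431542 it was -2.62 ± 0.42 for Clec4n, -2.47 ± 0.34 for Ccl12, 2.29 ± 0.46 for Angptl4, 1.57 ± 0.20 for Scara5 and 1.38 ± 0.23 for Chst1.

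Microglial markers moved apart under SB431542. A different share of microglia in those cultures would move the markers alike, but Cd68 exceeded Cx3cr1 by 2.93 ± 0.11 on the log2 scale, with markers on both sides of 0, which argues against share alone. Deviating vehicle libraries would shift all 3 comparisons alike, and 1 of the 5 listed markers, Cx3cr1, differed from the value or limit under another compound. For the other markers this cannot be told apart from an effect of SB431542, because values per sample were not analysed here. A change of state in microglia present in the cultures may contribute and stays untested.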

How the results depend on the processing

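The bound for genes in 1 table only was chosen after the data were seen, and the other alternatives before. An adjusted p under 0.01 left the counts of genes and of shared genes within 1.5 times, for all compounds and pairs. A fold limit of 1.5 lies beside the tables' own limit, and a mean count limit at the lower quartile keeps a fixed share of each table, so neither could move the counts of genes far. A 2-fold limit left 314 genes for SB431542, 86 for the RUNX1 inhibitor and 283 for HLM006474, since fewer genes pass it. Of the 8 list directions past the test, 5 passed when genes in several lists were left out, where the lists are smaller, and 6 under either of the stricter p and count limits. For the difference between HLM006474 and the RUNX1 inhibitor the 20 genes became 34 with the vehicle covariance taken out and 7 at an adjusted p under 0.01. With genes in 1 table only added, the differences numbered 48 for HLM006474 and the RUNX1 inhibitor, 179 for HLM006474 and SB431542, and 126 for the RUNX1 inhibitor and SB431542, because more genes are tested. Of 231 named values, 206 passed an adjusted p under 0.01 and 126 a 2-fold limit. No paired analysis was possible because the tables hold no values per sample. For the same reason the tests on counts, other normalisations, a count filter, the replicate block, leave-one-out and other splits of the samples were not run. Genes under the fold limit are outside the tables, and at least 2400, 2393 and 3016 more genes passed the adjusted p under SB431542, the RUNX1 inhibitor and HLM006474, so a gene missing from a table is not shown to be unchanged. Low counts limit 76 genes of the SB431542 table and 69 of the HLM006474 table, which have mean counts under 20.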

Other observations

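The gene groups in this part were chosen after the values were seen, except the oligodendrocyte lineage list and the genes in all 3 tables, and the tests of explanations were chosen after the results were seen. Of 18 immediate early genes, which cells switch on within minutes of a stimulus, 8 were listed for SB431542, 7 for the RUNX1 inhibitor and 10 for HLM006474, all higher. Egr1 stood at 0.82 ± 0.10, 0.62 ± 0.10 and 1.41 ± 0.095 in the authors' deposited tables. Of 20 chemokine genes 10 were listed under SB431542, all higher, 1 under the RUNX1 inhibitor, lower, and 4 under HLM006474, 2 of them higher. Under SB431542 they included Ccl4 at 2.89 ± 0.23 and Ccl3 at 1.78 ± 0.18 in the authors' deposited table. Of 18 C-type lectins and scavenger receptors, 13 were higher and 1 lower under SB431542, 1 higher and 1 lower under the RUNX1 inhibitor, and 4 higher and 1 lower under HLM006474. Among those higher under SB431542 were Marco at 2.26 ± 0.52 and Clec4e at 1.99 ± 0.49 in the authors' deposited table. Of 14 genes of resident microglia, 8 were lower under SB431542, 1 under the RUNX1 inhibitor and 4 under HLM006474, and none higher. Under SB431542 these included Olfml3 at -1.26 ± 0.075 in the authors' deposited table.

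Of 13 heme and iron genes 8 were higher under HLM006474, 4 under SB431542 and none under the RUNX1 inhibitor. Under HLM006474 they included the transferrin receptor gene Tfrc at 1.59 ± 0.31 and biliverdin reductase Blvrb at 1.28 ± 0.13 in the authors' deposited table. Of 8 pentose phosphate and NADPH genes 3 were listed under HLM006474 and none under the other compounds. They were G6pdx, Pgd and Taldo1, all higher, at 0.80 ± 0.060, 0.83 ± 0.069 and 0.79 ± 0.066 in the authors' deposited table. Of 24 Fanconi anemia and homologous recombination genes, 12 were lower under HLM006474 and 7 under the RUNX1 inhibitor, and none was listed under SB431542.

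Under HLM006474, 7 of 12 oligodendrocyte lineage markers fell. A hypothesis of fewer such cells needs similar falls. The highest of the 7 listed markers exceeded the lowest by 0.97 ± 0.55 on the log2 scale, which is under 3 standard errors and does not exclude it. The remaining markers have no value in the table, so this cannot be told apart from a change within the cells. Deviating vehicle libraries also stay open, since 0 of the 7 markers differed from the values or limits under the other compounds.

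Of the 55 genes that moved one way in all 3 tables, 34.5% had fold changes that differed between the compounds, 7 of the 17 higher and 12 of the 38 lower genes. A difference of the vehicle cultures that all 3 comparisons share would give equal changes, which argues against it as the whole account for those genes. For the others it cannot be told apart from a response that the compounds share, because all comparisons use the same 4 vehicle samples. A response to handling or to any added compound may contribute and was not tested.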
